A study of Homo sapiens with 2 samples.

How the data were processed

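Messenger RNA was measured in 2 libraries of Hep3B cells, an established human hepatocellular carcinoma line known to lack p53. One library came from cells given dimethyl sulfoxide (DMSO), the solvent control, and the other from cells given an extract of the coastal plant Glehnia littoralis (GLE). Per the labels, 500 ng of total RNA entered each library, made with a Lexogen QuantSeq kit, which reads the 3′ end of polyadenylated RNA. The labels describe exposures of 24 h at up to 500 µg/mL for a viability assay, and the dose and time of the sequenced cells are not given in the sources used here.

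The deposited files hold raw read counts per gene symbol, 1 file per library, as whole numbers without normalization. Trimming with fastp, alignment with STAR, counting with HTSeq and the genome build GRCh38 are named in the submitters' processing notes. Tool versions, gene annotation and the strand setting of the counting are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart, and genes with near-identical copies, such as the MT1 metallothioneins, HSPA1A and HSPA1B, the CXCL1 to CXCL3 chemokines and ribosomal protein pseudogenes, carry uncertain counts. Of the 43424 symbols in the files, 42739 matched the RefSeq gene table of GRCh38, from which gene positions were taken.

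Counts were scaled by effective library sizes from the trimmed mean of M-values (TMM) in edgeR 4.0.16 under R 4.3.3. The factors were 1.03 for the control and 0.972 for the GLE library. For each gene, the ratio of GLE over control was computed from the scaled counts, with an exact Clopper-Pearson 95% interval of the GLE share of the gene's counts turned into a ratio. Intervals and detection floors cover counting error only, and treat each read as an independent molecule. Reads without molecular identifiers are not independent molecules, so counting error can be larger than the intervals show. With 1 library per group there is no residual degree of freedom, so no test between conditions was made. The size of a difference is described for these libraries alone. Genes with at least 30 counts summed over both libraries were kept, and log2 ratios had 0.5 added to each count. CPM values were computed from the deposited counts, scaled to the effective library size. A gene with 0 counts in one library was compared with a floor of 3 counts in that library.

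The comparison, the gene lists, the rule for naming genes and the other settings to be tried were fixed before the data were examined. There were 29 pathway lists and 3 lists of markers of other cell types. For each list with at least 5 measured members, the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. That percentile describes these libraries, and genes are not independent replicates. Intervals of list medians came from 2000 resamples of the members. Named genes were the 12 highest and the 12 lowest by the bound of the counting interval nearest to 1, up to 4 members of each list by the same measure, 13 genes named whatever their values (among them BAX, BCL2, BCL2L1, MCL1, CASP8, CASP9, CDKN1A, DDIT3, CYP1A1, HMOX1, ALB and AFP), and the 5 genes with most counts in each library. Identifiers without a symbol, mitochondrial ribosomal RNA and Y-linked or X-inactivation transcripts did not enter the ranking of highest and lowest genes. Some genes that this rule names are not reported here.

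The level of differences that counting error alone would give was found from 100 draws in which every gene had a ratio of 1 and reads were independent. The computation was tested on simulated data with 200 changed genes among the real genes, of which 11051 passed the filter. A ratio beyond 2-fold was found for 100% of the 50 genes simulated at 4-fold higher, for 97.8% of the 46 genes at 0.25, and for 0.589% of the 10857 unchanged genes. Genes simulated at exactly 2-fold passed in 50% of cases. The simulated counts varied by counting error alone, so these shares do not cover variation between cultures or preparations.

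The other settings were scaling by total counts, by DESeq2 1.42.0 size factors, by upper-quartile factors and by centring the median of genes with at least 100 counts. They also included minimums of 10 and 100 counts or none, a count of 2 added before the logarithm, thinning the deeper library to the shallower, library sizes without the 20 most abundant and the mitochondrial genes, and a criterion on the whole interval. Removal of a trend with transcript GC content was added after seeing the data, with a lowess span of 0.3 over genes with at least 100 counts and GENCODE release 29 coding transcripts. Python 3.11.15, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.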

Results

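The series asked whether GLE acts on Hep3B hepatoma cells, with apoptosis named as its interest. Gene-level read counts were obtained from 1 DMSO control library and 1 GLE-treated library. The control held 5618328 counts and the GLE library 3636351. A count was present for 16505 genes in the control and 16539 in the GLE library, and 12189 and 11280 genes had 10 or more. A floor of 3 counts corresponded to 0.519 CPM in the control and 0.848 CPM in the GLE library. Mitochondrial ribosomal RNA took 8.52% of control counts (Clopper-Pearson 95% interval 8.50 to 8.55) and 13.2% of GLE counts (13.1 to 13.2). RNR2 held the most counts in both libraries, at 6.06% and 9.76%. COX3, RNR1, ATP6 and COX2 followed in the control, and RNR1, ND4, ATP6 and COX2 in the GLE library.

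Members of the integrated stress response and heat shock lists leaned higher in the GLE library, and liver transcription factors and NF-kB targets leaned lower. ATF3, a stress-induced transcription factor on chromosome 1 (212565407 to 212620777, GRCh38), was 12.0-fold higher (95% counting interval 10.4 to 13.8). DNAJB1, a heat shock co-chaperone, was 7.95-fold higher (7.37 to 8.57). NR0B2, a nuclear receptor that represses bile acid synthesis on chromosome 1 (26911489 to 26913975), was 15.6-fold lower (8.78 to 30.4). ID1, a target of BMP signalling in the list of TGF-beta and Wnt feedback genes, was 5.46-fold lower (4.58 to 6.57). Of 11068 measured genes, 1056 (9.54%) were at least 2-fold higher and 1164 (10.5%) at least 2-fold lower in the GLE library. Counting error alone gave a mean of 20.3 higher and 42.3 lower genes in 100 draws. The whole counting interval lay beyond 2-fold for 423 higher and 316 lower genes, against a mean of 0.04 genes from counting error alone. These differences have no replicate check, and variation between cultures cannot be separated from an effect of the extract.

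**Figure D1:**
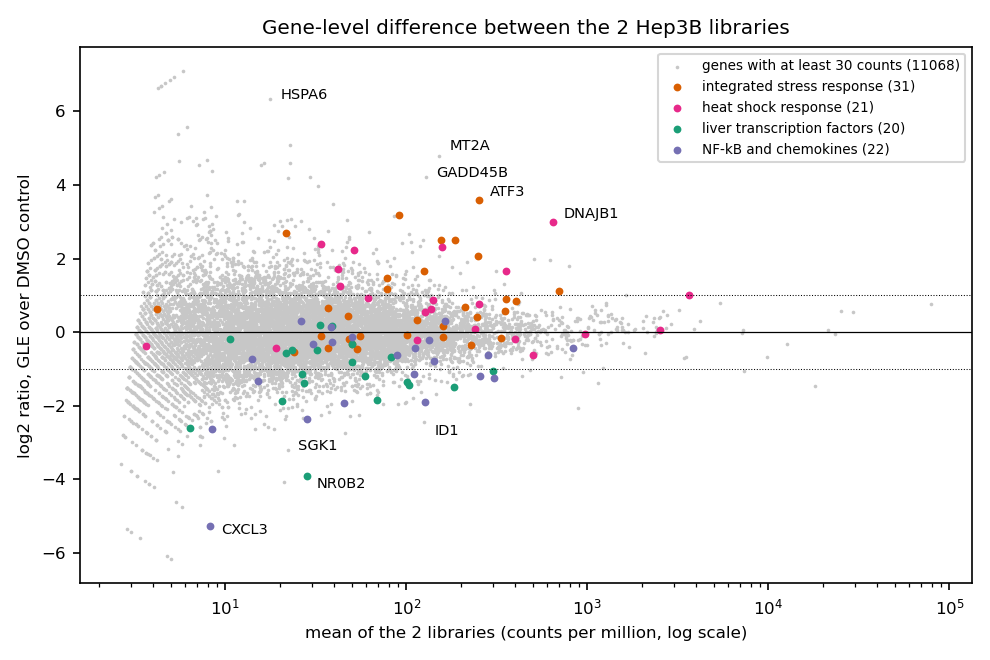
Log2 ratio of GLE over control (vertical axis) against the mean level of the 2 libraries in CPM (horizontal log axis) for 11068 genes, 1 point per gene, with 4 fixed lists in colour and dotted lines at 2-fold. ATF3 and DNAJB1 lie far above 0 and NR0B2, CXCL3 and ID1 far below it.

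Among the genes with the largest cautious ratios, HSPA6, an inducible HSP70 chaperone on chromosome 1 (161524540 to 161526894), had 2 control and 124 GLE counts, a ratio of 101 (27.5 to 846). MT2A, a metal-binding metallothionein on chromosome 16 (56608584 to 56609497), was 27.6-fold higher (21.3 to 36.4). GADD45B, a stress-inducible growth arrest gene, was 18.5-fold higher (14.6 to 23.8), and CDKN2D, an inhibitor of CDK4 and CDK6, was 25.2-fold higher (13.3 to 53.5). MT1E had 1 control and 43 GLE counts, a ratio of 70.3 (12.0 to 2839). Control counts were 0 for CFAP53, MT1G, RPL13AP3, DHRS2, ZNF14, NPR3 and BNIPL. Against the floor of 3 control counts, these were at least 22.3-fold, 20.2-fold, 19.1-fold, 18.0-fold, 16.9-fold, 16.9-fold and 16.3-fold higher, in that order, and the lower ends of their counting intervals, which also take in the error of the GLE count, ran from 17.4 down to 12.5. RPL13AP3 is a ribosomal protein pseudogene whose reads can be shared with its parent.

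At the other end, CXCL3, a neutrophil chemokine on chromosome 4 (74036589 to 74038689), had 94 control counts and 1 GLE count, 57.5-fold lower (10.1 to 2296). SMIM32 and FAM133CP also had 1 GLE count each, and were 56.9-fold (9.97 to 2272) and 39.8-fold (6.89 to 1595) lower. GLE counts were 0 for CEBPA-DT, PRKCH, CAVIN2-AS1 and H1-1. Against the floor of 3 GLE counts, these were at least 11.8-fold, 7.96-fold, 7.14-fold and 6.73-fold lower. The upper ends of their ratio intervals were 0.107, 0.162, 0.182 and 0.193. These ends also take in the error of the control count and allow smaller falls. CEBPA-DT is a divergent transcript beside CEBPA. TCIM was 15.1-fold lower (5.73 to 56.7), and SGK1, a kinase induced by glucocorticoids, was 9.42-fold lower (5.6 to 17.1). Counts of the mitochondrial transfer RNAs TRNS2 and TRNY were 17.7-fold (8.82 to 41.4) and 6.70-fold (4.88 to 9.43) lower.

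Apoptosis genes did not lie to one side. BCL2L11, which encodes the BH3-only killer BIM, was 3.84-fold higher (2.86 to 5.20), and APAF1, the apoptosome scaffold, was 2.64-fold higher (1.90 to 3.68). FADD, the adaptor of death receptors, was 3.0-fold lower (2.46 to 3.68), and BOK was 3.67-fold lower (2.11 to 6.83). Of 29 measured pro-apoptotic genes, 2 were at least 2-fold higher and 3 at least 2-fold lower, and the interval excluded 1 for 6 higher and 10 lower genes. Over all 10315 measured protein-coding genes, the interval lay above 1 for 2859 and below 1 for 3104. That is the background for such counts in each list. The median log2 ratio of the pro-apoptotic genes was -0.20, at percentile 15.9 of matched random lists. BAX, at 1.16 (0.682 to 1.95), CASP8, at 0.821 (0.638 to 1.05), and CASP9, at 1.96 (0.933 to 4.18), showed no difference detectable at this depth.

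Anti-apoptotic genes had a median log2 ratio of -0.05 over 15 measured members, at percentile 40.7. BIRC3, an inhibitor of apoptosis induced by NF-kB, was 2.19-fold lower (1.90 to 2.54) and the only member beyond 2-fold. MCL1 was 1.58-fold higher (1.44 to 1.73), BAG4 1.77-fold (1.47 to 2.14) and DAD1 1.46-fold (1.28 to 1.68). BCL2L1 had a ratio of 0.879 (0.757 to 1.02). BCL2 had 0 counts in both libraries, so its level lay under the floor in each.

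The integrated stress response list had 10 of 31 measured members at least 2-fold higher and 0 at least 2-fold lower. Its interval lay above 1 for 19 members and below 1 for 6. The median log2 ratio was 0.58 (interval of resampled members -0.07 to 0.91), at percentile 100 of random lists. DDIT3, the stress transcription factor CHOP on chromosome 12 (57516588 to 57520517), was 9.17-fold higher (7.42 to 11.4). CHAC1, a glutathione-degrading enzyme, was 5.72-fold higher (5.05 to 6.5), and PPP1R15A, a phosphatase subunit that reverses eIF2 phosphorylation, 5.63-fold (4.91 to 6.47). Endoplasmic reticulum chaperones and unfolded protein response genes had 5 of 23 members at least 2-fold higher and a median of 0.24, at percentile 96.9. DNAJB9 and HERPUD1 were 8.40-fold (6.32 to 11.3) and 5.04-fold (4.33 to 5.88) higher, followed by ERO1B at 3.81-fold (1.88 to 8.23) and SEC61B at 2.09-fold (1.88 to 2.32).

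Heat shock genes were higher for 8 of 21 members by at least 2-fold and lower for 0, with a median log2 ratio of 0.76 (0.06 to 1.25) at percentile 100. DNAJB4 was 5.32-fold (3.99 to 7.20), HSPA1A 4.94-fold (4.34 to 5.64) and the co-chaperone BAG3 4.67-fold (3.73 to 5.89) higher. HSPA1A shares nearly all of its sequence with HSPA1B. Metallothionein and zinc genes had 4 of 7 members at least 2-fold higher, which were the metallothioneins MT1E, MT1G, MT1X and MT2A. The list's median of 3.39 (-0.21 to 5.57) was the same with MT1G placed at its bound, but was 0.22 over the 4 members with at least 100 counts, of which MT2A is the sole metallothionein. MT1X was 11-fold higher (5.22 to 26.8). Among 27 NRF2 targets, 4 were at least 2-fold higher and 1 lower, with a median of 0.10 at percentile 84.4. Of these, SLC7A11, the cystine transporter, was 3.15-fold (2.76 to 3.6), GCLM 2.99-fold (2.55 to 3.51), SRXN1 2.46-fold (2.14 to 2.85) and HMOX1, heme oxygenase, 2.19-fold (1.70 to 2.82) higher. Outside these lists, mitochondrial ribosomal RNA took a larger share of the GLE library, 13.2% against 8.52%, and a link to stress was not tested.

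Autophagy and lysosome genes had 7 of 31 members at least 2-fold higher and 0 lower, with a median log2 ratio of 0.33 at percentile 99.5. GABARAPL1 was 4.63-fold (3.63 to 5.95), ATP6V1H 2.93-fold (1.96 to 4.46), the initiating kinase ULK1 2.44-fold (2.17 to 2.73) and MAP1LC3B 2.42-fold (2.06 to 2.83) higher. The p53 target list had 7 of 25 members at least 2-fold higher and 1 lower, with a median of 0.25 at percentile 95.8, in a line known to lack p53. That median was 0.13 over the 18 members with at least 100 counts and 0.39 with the GC trend removed. SESN2 is also a member of the integrated stress response list. SERTAD1 was 16.1-fold (10.4 to 26.3), SESN2 4.23-fold (3.83 to 4.68), BTG2 3.73-fold (1.94 to 7.58) and GADD45A 3.24-fold (2.56 to 4.11) higher. CDKN1A, the cell cycle inhibitor p21, was 1.90-fold higher (1.63 to 2.23). Immediate early genes lay on both sides, with 9 of 21 at least 2-fold higher and 5 lower, and a median of 0.60 (-0.27 to 1.54) at percentile 99.97. Over the 13 members with at least 100 counts the median was 0.16. DUSP5 was 5.86-fold (3.03 to 12.2) and JUN 3.21-fold (2.98 to 3.47) higher, while IER3 was 3.70-fold lower (3.18 to 4.34).

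**Figure D2:**
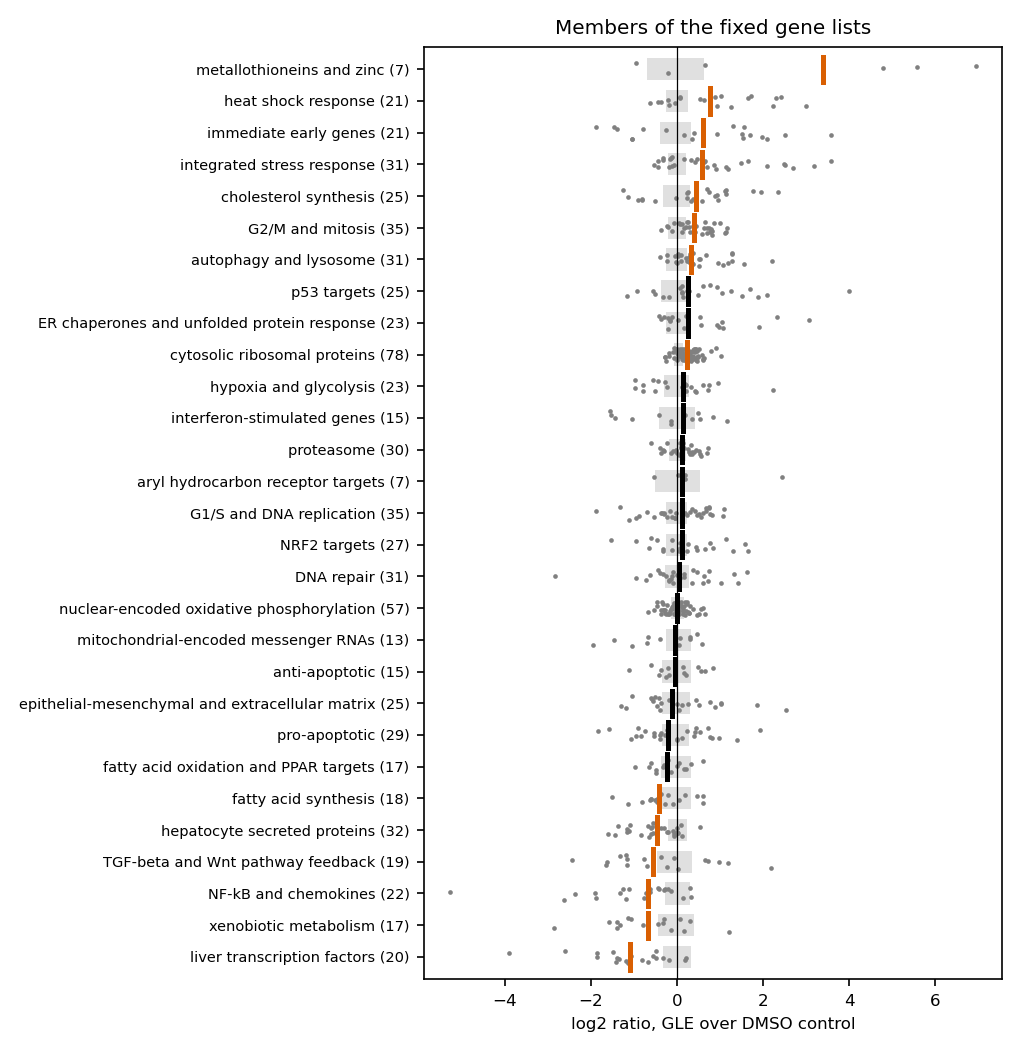
Log2 ratio of GLE over control for the measured members of 29 fixed lists (grey points, members in brackets), with the list median (bar) and the central 95% of medians of matched random lists (grey band); orange bars lie outside the band. Heat shock and integrated stress response medians lie at 0.76 and 0.58, and that of liver transcription factors at -1.10.

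Liver transcription factors were lower as a group. At least 2-fold lower values were found for 11 of 20 members and higher values of that size for 0, and the interval lay below 1 for 17. Their median log2 ratio was -1.10 (-1.41 to -0.53), at percentile 0. Besides NR0B2, ONECUT1 was 3.62-fold lower (2.94 to 4.49). CEBPA and HNF4A, named after their values were seen, had ratios of 0.357 and 0.372. Of 32 hepatocyte secreted proteins, 7 were at least 2-fold lower and 0 higher, with a median of -0.48 (-0.61 to -0.20) at percentile 0.01. KNG1, a kininogen, was 3.07-fold (2.34 to 4.09), the fibrinogen genes FGA and FGB 2.72-fold (2.23 to 3.33) and 2.23-fold (1.85 to 2.70), and APOB, the apolipoprotein of LDL, 2.61-fold (2.49 to 2.74) lower. ALB, albumin, was 1.60-fold (1.56 to 1.64) and AFP, the hepatoma marker alpha-fetoprotein, 1.39-fold (1.31 to 1.48) lower.

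Xenobiotic metabolism genes had 7 of 17 members at least 2-fold lower and 1 higher, and a median log2 ratio of -0.68 at percentile 0.14. The sulfotransferases SULT1E1, SULT1A1 and SULT2A1 were 7.73-fold (3.77 to 18.4), 3.0-fold (2.22 to 4.13) and 2.52-fold (1.73 to 3.75) lower, and the glucuronosyltransferase UGT2B4 was 2.21-fold lower (1.54 to 3.24). ABCC2, a canalicular efflux pump listed among NRF2 targets, was 2.90-fold lower (2.58 to 3.28). Aryl hydrocarbon receptor targets had a median of 0.11 over 7 members, at percentile 71.2. CYP1A1, the classic target of that receptor, had a ratio of 1.02 (0.808 to 1.27), and TIPARP was 5.41-fold higher (4.55 to 6.46). NFE2L2 had a ratio of 1.14 (1.05 to 1.23). SLC7A5, also a member of the integrated stress response list, was 1.46-fold lower (1.10 to 1.97).

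NF-kB targets and chemokines were lower, with 9 of 22 members at least 2-fold lower and 0 higher. The interval lay below 1 for 16 and above 1 for 1, and the median log2 ratio was -0.68 (-1.25 to -0.37), at percentile 0. CXCL2 was 6.5-fold (3.15 to 15.5) and CXCL1 5.22-fold (3.61 to 7.79) lower, and these chemokine genes share much of their sequence. Interferon-stimulated genes had 1 of 15 members at least 2-fold higher and 4 lower, with a median of 0.13 at percentile 76.3. IFI35, IFI6 and STAT2 were 2.98-fold (1.73 to 5.47), 2.97-fold (1.97 to 4.64) and 2.10-fold (1.48 to 3.03) lower, and HLA-C was 1.79-fold higher (1.47 to 2.19). Feedback genes of the TGF-beta and Wnt pathways had 7 of 19 members at least 2-fold lower and 2 higher, with a median of -0.57 at percentile 0.98. The interval of resampled members, -1.16 to 0.02, included 0. RNF43 was 3.15-fold (2.25 to 4.49) and DKK1 2.52-fold (2.11 to 3.03) lower, and NOTUM 4.72-fold higher (2.14 to 11.4). Mesenchymal and matrix genes had 4 of 25 members at least 2-fold higher and 3 lower, with a median of -0.12 at percentile 27.8. SNAI1 was 5.99-fold (2.81 to 14.2) and S100A4 3.71-fold (1.76 to 8.36) higher, and MYL9 2.5-fold lower (1.60 to 4.04).

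Genes of G2/M and mitosis were higher by small amounts, with the interval above 1 for 25 of 35 and below 1 for 2. Their median log2 ratio was 0.40 (0.22 to 0.68), at percentile 99.98, and 4 were at least 2-fold higher. ANLN was 2.23-fold (1.97 to 2.52), TTK 2.20-fold (1.75 to 2.77), CKS2 2.16-fold (1.77 to 2.64) and TACC3 1.77-fold (1.65 to 1.89) higher. G1/S and replication genes had 2 of 35 members at least 2-fold higher and 3 lower, with a median of 0.11 at percentile 87.1. UHRF1 was 3.88-fold (1.90 to 8.91), cyclin E1 (CCNE1) 2.54-fold (1.87 to 3.52) and UNG 1.93-fold (1.62 to 2.32) lower, and CDC6 2.10-fold higher (1.84 to 2.39). DNA repair genes had 4 of 31 members at least 2-fold higher and 1 lower, with a median of 0.04 at percentile 62.6. LIG4, the ligase of end joining, was 7.75-fold lower (3.40 to 21.8). EXO1, XRCC4 and BLM were 3.07-fold (2.31 to 4.12), 2.67-fold (1.87 to 3.85) and 2.03-fold (1.67 to 2.48) higher.

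Cholesterol synthesis genes had 6 of 25 members at least 2-fold higher and 2 lower, with a median log2 ratio of 0.45 (0.22 to 0.92) at percentile 99.8. INSIG1 was 5.08-fold (3.82 to 6.82), MSMO1 3.86-fold (3.21 to 4.66) and MVD 3.44-fold (1.95 to 6.29) higher. Fatty acid synthesis lay the other way, with 2 of 18 members at least 2-fold lower, 0 higher and a median of -0.43 at percentile 0.98. GPAM was 2.91-fold (1.78 to 4.97), FASN 1.75-fold (1.59 to 1.92) and ACSL4 1.54-fold (1.40 to 1.70) lower, and PLIN2, a lipid droplet protein, 1.52-fold higher (1.46 to 1.58). Fatty acid oxidation and PPAR targets had a median of -0.23 over 17 members, at percentile 13.1. In that list SLC25A20 was 2.0-fold (1.37 to 2.98) and CPT1A 1.41-fold (1.26 to 1.57) lower, and FABP1 1.24-fold higher (1.12 to 1.38). Hypoxia and glycolysis genes had a median of 0.15 over 23 members, at percentile 87.7. ADM was 4.74-fold (2.81 to 8.32) and KDM3A 1.93-fold (1.57 to 2.38) higher, and CA12 and NDRG1 were 1.98-fold (1.63 to 2.43) and 1.97-fold (1.64 to 2.39) lower.

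Cytosolic ribosomal protein genes were slightly higher, with the interval above 1 for 59 of 78 and below 1 for 7. Their median log2 ratio was 0.22 (0.14 to 0.29), at percentile 99.97, and they took 9.22% of control and 10.3% of GLE counts. RPL23A, RPL10, RPL30 and RPS12 were 2.01-fold (1.95 to 2.08), 1.88-fold (1.68 to 2.12), 1.74-fold (1.67 to 1.80) and 1.53-fold (1.49 to 1.56) higher. Proteasome genes had a median of 0.12 over 30 members, at percentile 85.6. PSMC6, PSMC2 and PSMD14 were 1.64-fold (1.40 to 1.93), 1.62-fold (1.42 to 1.84) and 1.47-fold (1.35 to 1.60) higher, and PSMC4 1.52-fold lower (1.39 to 1.67). Nuclear-encoded oxidative phosphorylation genes had a median of 0.00 over 57 members, at percentile 46.5, with 0 beyond 2-fold either way. COX7B, NDUFA8 and UQCRB were 1.56-fold (1.39 to 1.74), 1.51-fold (1.32 to 1.73) and 1.42-fold (1.31 to 1.54) higher, and CYC1 1.60-fold lower (1.42 to 1.80).

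Mitochondrial-encoded messenger RNAs lay on both sides of 1. Counts of ND6 were 3.90-fold (3.47 to 4.4), COX3 2.76-fold (2.73 to 2.79), ND3 2.07-fold (2.03 to 2.10) and ATP8 1.61-fold (1.59 to 1.63) lower. With the strand setting not given, antisense reads cannot be told apart, so counts of ND6 need not measure its level. ND4 was 1.5-fold higher (1.48 to 1.51), and the ribosomal RNAs RNR2 and RNR1 were 1.70-fold (1.70 to 1.71) and 1.46-fold (1.45 to 1.47) higher. ATP6 had a ratio of 0.964 (0.956 to 0.973) and COX2 of 1.04 (1.03 to 1.05), the latter below 1 when scaled by total counts. The 13 messages had a median log2 ratio of -0.05, at percentile 27.8, with 6 intervals above 1 and 7 below. Together they took 13.7% of control and 11.3% of GLE counts.

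**Figure D3:**
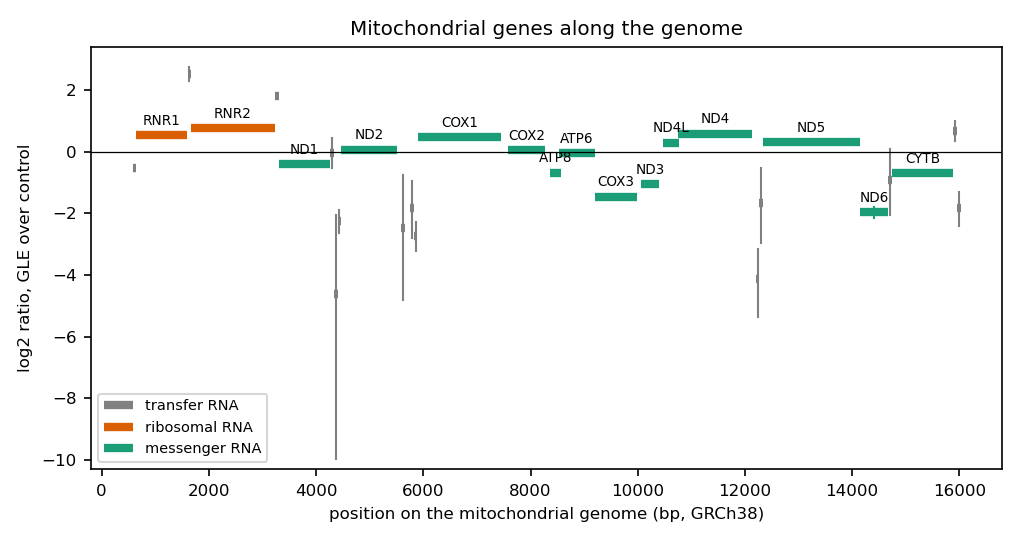
Log2 ratio of GLE over control (vertical axis) against position on the mitochondrial genome in bases (horizontal axis), with each gene drawn over its length and a vertical line for its 95% counting interval. ND6 and COX3 lie lowest among the messages and ND4 highest, and both ribosomal RNAs lie above 0.

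Markers of other cell types were measured in small number. Of 11 fibroblast markers, COL1A1 alone reached the count minimum, with 4 control and 29 GLE counts, an 11.8-fold ratio (4.16 to 46.4). Of 10 endothelial markers, PECAM1 alone did, with 36 control counts and 1 GLE count, 22-fold lower (3.71 to 894). Of 17 leukocyte markers, 4 did. CD14 was 2.52-fold lower (1.19 to 5.93), LYZ, with 2711 control and 1540 GLE counts, 1.08-fold lower (1.01 to 1.15), and CD68 1.34-fold higher (1.01 to 1.77).

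Of the 29 list medians, 8 lay above and 6 below the central 95% of their random lists. If lists, and the genes within each list, varied independently, 1.45 would be expected outside. Genes of a pathway can vary together between cultures, which random lists of unrelated genes do not cover. The number expected outside without treatment is therefore not known from 1 library per group. Some lists share members, such as ATF3 in the integrated stress response and immediate early lists. SLC7A11 is in the integrated stress response and NRF2 lists.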

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

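Removal of the GC trend was chosen after seeing the data. The count of genes at least 2-fold higher, 1056, was 1655 with a minimum of 10 counts, 613 with 100, 4197 with no minimum and 423 when the whole counting interval had to lie beyond 2-fold. The count lower, 1164, was 1840, 579, 3222 and 316 under the same settings, which by construction change the number of genes that can pass. Other settings kept both counts within 1.5 times, from 906 to 1104 higher and from 892 to 1352 lower. Among these, removal of the GC trend and thinning also left fewer genes, 10339 and 10577 against 11068. Scaling by total counts gave 914 higher and 1352 lower and moved the median of genes by -0.08, the largest shift among the settings. All 260 alternative list medians stayed within the interval of resampled members, which is wide for some lists. With a minimum of 100 counts the metallothionein and zinc median went from 3.39 to 0.22 and the immediate early median from 0.60 to 0.16, as fewer members were left. Medians near 0 changed sign for oxidative phosphorylation and DNA repair (-0.08 and -0.04 under total counts) and for mesenchymal genes (0.04 with the GC trend removed). The mesenchymal median of -0.12 also went the other way, to -0.40, over the 19 members with at least 100 counts. Of the values for 151 named genes, 858 stayed within the counting interval, 41 moved outside it and 1 reversed. That was COX2, whose log2 ratio of 0.05 became -0.026 under total counts, a scaling that lowers each of the 151 genes by about 0.08 alike. Leaving out a replicate was not possible with 1 library per group. No paired analysis was possible because each group has 1 library. Depth limits genes near the minimum of 30 counts, and the GLE library is the shallower.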

Other observations

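The tests of differences between cultures, of AU-rich elements and of the mitochondrial RNAs were chosen only after the results were seen, as were the genes and groups of the next paragraphs.

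Counts assigned to small nucleolar RNA and Y RNA genes were higher in the GLE library, and those of most measured transfer RNA genes lower. The kit reads polyadenylated RNA, and these classes, RN7SK and many histone messages largely lack such tails. Their counts therefore need not measure the level of the RNA. Of 25 small nucleolar RNA genes, 16 were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.25 (interval of resampled members 0.55 to 2.12). SNORD63 had 41 control and 110 GLE counts, a ratio of 4.38. All 3 measured Y RNA genes were at least 2-fold higher, among them RNY4 with 9 and 44 counts. RN7SK, a regulator of transcription elongation, had 17 control and 198 GLE counts, a ratio of 19.0. Histone genes had a median of 0.74 (0.46 to 1.34) over 15 genes, of which 6 were at least 2-fold higher and 1 lower, with the interval above 1 for 11 and below 1 for 2. H1-2 had a ratio of 2.65 and H2AZ1 of 0.903, and H1-1 had 33 control and 0 GLE counts. Mitochondrial transfer RNAs had a median of -1.68 over 14 genes, though TRNV and TRNL1, which flank the ribosomal RNA RNR2, had ratios of 5.72 and 3.50. Of 6 nuclear transfer RNA genes, 4 were at least 2-fold lower and 2 higher, with a median of -1.56 (-2.21 to 2.11).

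Coding genes with 1 exon leaned lower. Of 168, 58 were at least 2-fold lower and 19 higher, with a median log2 ratio of -0.59 (-0.82 to -0.32), against -0.03 (-0.04 to -0.01) over 8434 genes with 5 or more exons. With the GC trend taken out the median was -0.51 (-0.74 to -0.18). SOX4, a developmental transcription factor, had 8223 control and 1214 GLE counts, a ratio of 0.241, and FOXQ1 a ratio of 0.205. Genes outside the fixed lists with high ratios included the clock gene PER1 at 11.4, CREBRF at 9.01 and the growth factor HBEGF at 8.30.

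The integrated stress response, heat shock and metallothionein lists, grouped after their medians were seen, had a joint median log2 ratio of 0.64 (0.33 to 0.93) over 59 members. Taken singly, the interval of the median included 0 for the first (-0.07 to 0.91) and the last (-0.21 to 5.57), and the endoplasmic reticulum, NRF2 and p53 lists, with medians of 0.24, 0.10 and 0.25, stayed inside their random range. Across 8135 genes, which are not independent replicates, the ratio was lower at higher transcript GC content (Spearman rho -0.19), but the joint median after that trend was removed was 0.70 (0.25 to 1.02, 57 members). A response to GLE is a candidate explanation, and a difference between the 2 cultures or preparations cannot be told apart from it with 1 library per group.

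The liver transcription factor and NF-kB lists were lower over 42 members. Their median of -0.79 was -0.90 (-1.21 to -0.52) with the GC trend removed, so a trend with GC content of the whole transcript does not account for it. A trend with GC content of the 3′ end alone was not tested, here or for the stress lists. Genomic DNA in the control would also reach silent genes, but 381 olfactory receptor genes held 0.0394 control counts each, against a median loss of 139 counts per member. A general loss of messages rich in AU elements would lower the 761 genes with most ATTTA motifs per length of 3′ untranslated region. Their GC-corrected median was 0.071 (0.01 to 0.14). The 37 list members with a value had a median of 1.82 motifs per kb, against 1.78 over all genes compared. Decay of single AU-rich members was not tested. A loss of transcription factor messages of every family would lower zinc finger genes, whose GC-corrected median was 0.18 (0.06 to 0.28, 331 genes). Zinc finger genes do not stand for other families of transcription factors, so a wider loss among those is not excluded. An effect of GLE was not tested apart from a difference between cultures, and both stay open.

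Among the 13 mitochondrial messages and both ribosomal RNAs, the highest ratio, 1.70 for RNR2, was 6.65 times the lowest, 0.256 for ND6. The next lowest was 0.362 for COX3, so the span rests in part on ND6. ATP8 and ATP6 share an RNA, and the ATP8 ratio was 0.645 of the ATP6 ratio. A difference in where the libraries primed or the RNA was cut may contribute, since on the other shared RNA the upstream gene was again the lower, with an ND4L ratio 0.816 of that of ND4. These are values of 2 shared RNAs in 1 library per group, and they do not cover ND6, COX3 or the ribosomal RNAs. An effect of GLE on mitochondrial RNA was not tested.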
